A study of Homo sapiens with 9 samples.

How the data were processed

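The values used were the deposited log2 probe set signals, 1 column per array for 9 arrays, used as they were with no further transformation or added constant. The submitters' processing notes name RMA without a version; the software that ran it and the chip definition are not given in the sources used here. As a method, RMA corrects background, normalizes all arrays to 1 distribution and summarises the probes of a probe set by median polish. The deposited values bear this out in that they run from 2.66 to 15.0, with 0 missing values and array medians between 5.61 and 5.68. Per the labels' protocols, the cells were grown without phenol red and split the day before treatment, and labelled cRNA was made from total RNA in 1 cycle.

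Samples were grouped by treatment and time as the labels give them, into vehicle, GW7647 for 6 h and GW7647 for 24 h, with 3 arrays in each. The labels number the replicates but do not say that equal numbers belong together or that replicates are separate cultures. Replicate numbers were therefore left out of the model, and every p-value measures only the spread between these samples, which may be technical.

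Of 54675 probe sets, 62 were control probe sets, 41097 had 1 gene symbol by the annotation given, 1801 had several and 11721 had none. The 41091 probe sets with 1 symbol that are not controls were used; of the 41097, 41043 had an Entrez ID that matched the GRCh38.p14 gene table, which updated 0 symbols, and the 54 without a match kept the symbol of the probe table. Each gene was represented by its probe set with the highest mean over the 9 arrays, which gave 19775 genes, 9252 of them with 1 probe set and 10523 with several. No filter on signal was applied.

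Differences were tested with limma 3.58.1 in R 4.3.3, with the data.table package, version 1.17.8, for reading. Group means were fitted over all 9 arrays with lmFit and moderated with eBayes at default settings (6 residual and 11.0 total degrees of freedom). Each of 3 comparisons, 6 h against vehicle, 24 h against vehicle and 24 h against 6 h, was tested two-sided, adjusted by Benjamini-Hochberg over the 19775 genes, and called at an adjusted p under 0.05. The median standard error of a log2 change was 0.07. An exact permutation test of 3 arrays against 3 cannot give a p under 0.10.

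The 29 gene lists, written from general knowledge of liver and PPARα biology, were tested with camera at its preset correlation of 0.01, adjusted over the lists within a comparison, with at least 5 measured members asked of a list. Of 804 list members, 714 were measured. Some lists share members. Hypoxia and glycolysis share SLC2A3, PFKFB3, LDHA and others, and PPARα targets and mitochondrial oxidation share CPT1A, SLC25A20, ETFDH and others. Shifted lists are therefore not independent of one another. Camera with a correlation estimated for each list, and fry, were the other list tests. The lists covered classical PPARα targets, mitochondrial and peroxisomal fatty acid oxidation, omega-hydroxylation, ketone bodies, lipid droplets, fatty acid uptake, fatty acid synthesis, cholesterol, apolipoproteins, bile acids, glucose production, glycolysis, amino acids and urea, acute phase, inflammation, interferon, unfolded protein and amino acid stress, NRF2 targets, drug metabolism, nuclear receptors, the respiratory chain, cell cycle, growth arrest, immediate early genes, the circadian clock, hypoxia, hepatocyte identity and markers of other liver cell types.

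Genes were named by rule. For each comparison with vehicle these were the 8 largest rises and 6 largest falls among genes that passed and whose arrays lay entirely apart, and for 24 h against 6 h the 5 largest in each direction. Added to them were up to 2 members of each list with the largest change past the threshold, and 9 genes of PPARα biology whatever their test. Of these 9, 7 had a probe set with 1 symbol, and the other 2 were not analysed here. Further members of a list, at most 4 per list, were named only within its description, and genes outside these rules, chosen after their values were seen, appear only in the closing part.

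The groups, the tests, the lists, the rule for named genes and the alternatives were chosen before the data were examined. The alternatives were the replicate number as a block, only the compared groups in the fit, an intensity trend with a robust prior, genes above the median signal, the mean of all probe sets, no probe sets with shared probes (those ending in _x_at or _s_at), every probe set on its own, quantile normalization, median centring, array weights, an adjusted p under 0.01, at least a 1.5-fold change, and leaving out each array in turn. A constant of 32 added before the logarithm was planned for linear values only and did not apply.

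The expected relation between both comparisons that share the vehicle arrays was simulated 100 times with unchanged genes. Each gene had its observed spread, the same in all groups. A self-test changed 200 of 19775 genes by known amounts, 50 per fold, in 10 simulated data sets. At 1.2-fold 26.8% of the changed genes were recovered, at 1.5-fold 98.6% and at 2-fold 100%, and on average 4.75% of the calls were false. Unchanged genes beside the changed ones, in 24 h against vehicle, gave 8.2 calls per run on average. In 6 h against vehicle, where no gene was changed, there were 0.2 calls per run on average. Lists of 25 genes shifted by 0.2 log2 units were found in 100% of runs, and 0% of unchanged lists were called. The simulated genes varied independently of one another. These shares therefore do not measure how the list test behaves for lists of correlated genes. The promoter-occupancy part of the study was not used here.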

Results

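Gene expression was measured in HepG2, an established human hepatoma line that keeps many functions of liver cells, after exposure to GW7647, a synthetic agonist of the nuclear receptor PPARα, which fatty acids activate. The 9 Affymetrix 3′ expression arrays fell into 3 groups of 3: cells given 100 nM GW7647 for 6 h, cells given 100 nM GW7647 for 24 h, and cells given the DMSO vehicle. One vehicle group served both times, and its duration is not given in the sources used here, so exposure to the ligand and time in culture change together. Each array held log2 RMA values, and 19775 genes were tested. The series accompanies a survey of gene promoters occupied by PPARα, and its expression arrays address which transcripts differ after a short and after a longer exposure to the agonist. The number of arrays, 3 per group, limits the precision of every value.

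Arrays of the same group correlated at r = 0.997 to 0.999 across genes over 9 pairs, and arrays of different groups at 0.995 to 0.998 over 27 pairs; genes are not independent replicates. The first principal component held 36.6% of the variance and placed the 24 h arrays at 12.7 to 18.4 and the 6 h arrays at -12.9 to -8.68. The second held 19.6% and placed the vehicle arrays at 8.53 to 13.5 and the 6 h arrays at -8.91 to -7.75. The 3′ minus 5′ signal of actin, a sign of RNA integrity, was 0.28 ± 0.11 log2 units in vehicle, 0.29 ± 0.01 at 6 h and 0.32 ± 0.08 at 24 h (SD, n = 3 arrays). That of GAPDH was 0.045 ± 0.046 in vehicle, 0.055 ± 0.013 at 6 h and 0.020 ± 0.002 at 24 h. Its 24 h arrays (0.018 to 0.022) lay below its 6 h arrays (0.045 to 0.070). Of 28 measured markers of other liver cell types, 2 rose, 1 fell and 25 did not pass at 6 h, and at 24 h 2 rose, 0 fell and 26 did not pass. With 1 array left out, the 2 rises at 6 h became 0 without vehicle replicate 1 or 6 h replicate 1 or 2 and 1 without any other array.

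**Figure D1:**
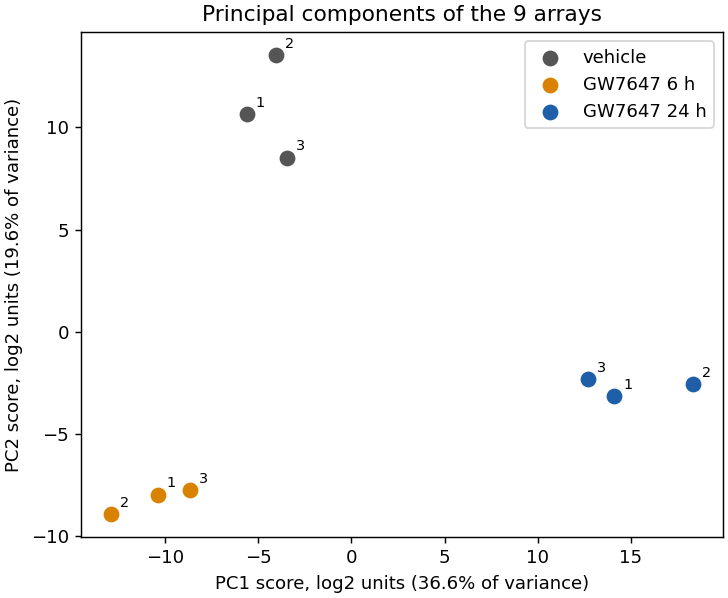
Principal components of the 9 arrays over 19775 genes, 1 point per array, with the share of variance on each axis. The 24 h arrays sit at 12.7 to 18.4 on the first component, and the vehicle arrays at 8.53 to 13.5 on the second.

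After 6 h of GW7647 the metallothioneins, small proteins that bind zinc and copper, had the largest rises together with CYP1A1, a cytochrome P450 of xenobiotic metabolism. MT1G was 5.35-fold (95% confidence interval 4.76 to 6.01) higher than in vehicle, with mean signals of 12.11 ± 0.12 against 9.69 ± 0.10 log2 units (SD, n = 3 arrays per group). CYP1A1 was 4.96-fold (95% confidence interval 4.41 to 5.58) higher, at 9.80 ± 0.14 against 7.49 ± 0.05 log2 units. PLIN2, which coats lipid droplets and is a textbook PPARα target, rose 2.05-fold (95% confidence interval 1.86 to 2.26), and the neutrophil chemokine CXCL8 rose 2.64-fold (95% confidence interval 2.28 to 3.05). The death ligand TNFSF10 fell 2.51-fold (95% confidence interval 2.19 to 2.88), and PPARA, which encodes the receptor itself, fell 1.53-fold (95% confidence interval 1.39 to 1.68). In all, 701 genes passed: 324 rose and 377 fell, 21 and 4 of them by more than 2-fold. Which direction had more genes depended on scaling, with 419 higher and 328 lower after quantile normalization and 255 and 416 after median centring.

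Log2 changes are given ± SE of the limma fit, with n = 3 arrays per group. Among the 8 largest rises, 7 were metallothioneins: MT1G (2.42 ± 0.08, adjusted p = 5.89e-08), MT1F (2.31 ± 0.09), MT1E (2.27 ± 0.08), MT1X (2.19 ± 0.08), MT1H (2.10 ± 0.08), MT1HL1 (1.99 ± 0.07) and MT2A (1.89 ± 0.08). Their probe sets carry the endings that mark probes shared between genes, so which member rose is uncertain, and a second MT1G probe set had a log2 change of 0.14. The largest falls were TNFSF10 (-1.33 ± 0.09, adjusted p = 1.65e-05), PTCHD4 (-1.06 ± 0.07), C9orf152 (-1.03 ± 0.13), PPP1R16A (-1.02 ± 0.07), the glutamate transporter SLC1A2 (-0.97 ± 0.19) and TOX3 (-0.83 ± 0.10). The SLC1A2 fall did not pass without vehicle replicate 1, vehicle replicate 3 or 6 h replicate 1, where its adjusted p reached 0.0701.

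Of the 23 measured classical PPARα targets, 4 rose, 0 fell and 19 did not pass, and the list was shifted upward. PPARα targets at 6 h had 5 up and 0 down adjusted over the list alone, with camera adjusted p = 0.00679 and adjusted p = 0.318 with an estimated correlation. The 4 were PLIN2 (1.04 ± 0.06, adjusted p = 8.57e-06), the carnitine carrier SLC25A20 (0.33 ± 0.06), ACSL1 (0.31 ± 0.06), which activates fatty acids, and VNN1 (0.30 ± 0.07). ACSL1 did not pass without 6 h replicate 1 or 2 (adjusted p up to 0.0700) or shared probes (0.16, adjusted p = 0.371), nor VNN1 without any 1 of the vehicle arrays, 6 h replicate 1 or 3 or 24 h replicate 3 (up to 0.136). The 4 rises of the list became 2 without 6 h replicate 1. A second PLIN2 probe set had a log2 change of -0.08. Other well-known targets did not pass at 6 h. The log2 change was -0.04 ± 0.10 for ANGPTL4 (adjusted p = 0.904), -0.05 ± 0.06 for FABP1 (adjusted p = 0.698) and 0.26 ± 0.13 for CREB3L3 (adjusted p = 0.386). PDK4, whose signal of 3.92 was near background, had 0.05 ± 0.13 (adjusted p = 0.908). CPT1A, which admits fatty acids to mitochondria, had 0.22 ± 0.09 (adjusted p = 0.250). It passed without vehicle replicate 3, with a log2 change of 0.33. All 9 probe sets of PPARA had a lower signal at 6 h, and the reported one changed by -0.61 ± 0.06 (adjusted p = 3.31e-04).

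Immediate early and serum response genes, which switch on within minutes to hours of a stimulus, were shifted upward at 6 h: of 30 measured, 12 rose, 0 fell and 18 did not pass. Immediate early genes at 6 h had 14 up and 1 down adjusted over the list alone, with camera adjusted p = 1.68e-08 and adjusted p = 0.137 with an estimated correlation. Their p was the smallest of the lists with camera at its preset correlation, whereas by fry, a rotation test, the cholesterol list had the smallest (adjusted p = 0.00200 against 0.00262). EGR1 (1.01 ± 0.11, adjusted p = 8.79e-04) and KLF10 (0.97 ± 0.11) led them. Cholesterol synthesis and uptake genes were also shifted upward, and of 23 measured members 7 rose, 1 fell and 15 did not pass. Cholesterol genes at 6 h had 8 up and 1 down adjusted over the list alone, with camera adjusted p = 4.57e-06 and adjusted p = 0.137 with an estimated correlation. HMGCS1, an early enzyme of sterol synthesis, rose by 0.69 ± 0.07 (adjusted p = 4.23e-04), and IDI1 by 0.48 ± 0.06, although a probe set of IDI1 without shared probes gave -0.038. INSIG2, which holds back sterol synthesis, was the member that fell (-0.38 ± 0.09). It did not pass without any 1 of the vehicle arrays, 6 h replicate 1 or 2 or 24 h replicate 3 (adjusted p up to 0.161). The inflammatory signalling list was shifted upward, and 7 rose, 2 fell and 19 did not pass of 28, led by CXCL8 (1.40 ± 0.10, adjusted p = 1.65e-05) and the chemokine CCL20 (0.84 ± 0.06). Inflammatory genes at 6 h had 7 up and 4 down adjusted over the list alone, with camera adjusted p = 0.0341 and adjusted p = 0.318 with an estimated correlation. So was the oxidative stress list of NRF2 targets, in which 5 rose, 1 fell and 23 did not pass of 29, with the metallothioneins MT1X and MT2A and the cystine transporter SLC7A11 (1.29 ± 0.09) as the largest. NRF2 targets at 6 h had 8 up and 2 down adjusted over the list alone, with camera adjusted p = 0.0341 and adjusted p = 0.560 with an estimated correlation. The median log2 change of this list was 0.0039 against a mean of 0.20, so the shift was not general to its members. It rests largely on a few large rises, among them MT1X and MT2A, which are read by probe sets with shared probes. The 7 cholesterol rises became 4 without 6 h replicate 1 or 2. The 5 NRF2 target rises became 3 without vehicle replicate 1 or 3 or any 1 of the 6 h arrays.

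Acute phase and complement genes, which encode plasma proteins made by the liver, were shifted downward at 6 h: 0 rose, 4 fell and 27 did not pass of 31. Acute phase genes at 6 h had 0 up and 10 down adjusted over the list alone, with camera adjusted p = 2.59e-06 and adjusted p = 0.137 with an estimated correlation. The 4 were haptoglobin HP (-0.40 ± 0.07), C4BPB (-0.31 ± 0.06), C1R (-0.26 ± 0.06) and the fibrinogen chain FGA (-0.25 ± 0.05). HP did not pass without 6 h replicate 2 (adjusted p = 0.0530), and without any 1 of the 6 h arrays C4BPB did not (up to 0.0765), nor with the replicate number as a block (0.0502). The same held for C1R (up to 0.124), also without vehicle replicate 2 or 3 or 24 h replicate 3, and for FGA (up to 0.102), also without vehicle replicate 1 or 2. Nuclear receptors and coregulators were shifted downward, and 1 rose, 3 fell and 22 did not pass of 26. Nuclear receptors at 6 h had 2 up and 7 down adjusted over the list alone, with camera adjusted p = 0.0110 and adjusted p = 0.137 with an estimated correlation. RXRA, the dimer partner of PPARα, fell by 0.64 ± 0.07 log2 units (adjusted p = 7.36e-04). The coactivator PPARGC1A and PPARA also fell (-0.64 ± 0.09 and -0.61 ± 0.06), and the glucocorticoid receptor NR3C1 rose (0.27 ± 0.06). NR3C1 did not pass without vehicle replicate 2 or 3 or any 1 of the 6 h arrays (up to 0.107). Hepatocyte identity genes were shifted downward, and 0 rose, 2 fell and 29 did not pass of 31. Hepatocyte identity genes at 6 h had 0 up and 3 down adjusted over the list alone, with camera adjusted p = 3.93e-04 and adjusted p = 0.137 with an estimated correlation. The transcription factors FOXA2 (-0.34 ± 0.06) and FOXA3 (-0.30 ± 0.06) were the 2. FOXA2 did not pass without 6 h replicate 2 (adjusted p = 0.0720), with probe sets averaged (-0.19, 0.142) or without shared probes (-0.21, 0.293). FOXA3 did not pass without vehicle replicate 2 or 3 or any 1 of the 6 h arrays (up to 0.141), with the replicate number as a block (0.0735) or with only the compared groups in the fit (0.0646). The 4 falls of acute phase genes became 0 without 6 h replicate 2 and 1 without 6 h replicate 1 or 3 and 2 without vehicle replicate 2. The 2 falls of hepatocyte identity genes became 0 without 6 h replicate 2 and 1 without vehicle replicate 2 or 3 or 6 h replicate 1 or 3. The 3 falls of nuclear receptors became 6 without 24 h replicate 2. Outside the shifted lists, DDIT4 (1.29 ± 0.09), a brake on growth signalling, and the glucose transporter SLC2A3 (0.83 ± 0.06) rose.

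The limma test passed 701 genes at an adjusted p under 0.05, against 3227 at an unadjusted p under 0.05. In all 701 the 3 arrays at 6 h lay entirely above or below the 3 vehicle arrays, as did 20.8% of all genes where chance gives 10%. The count was 261 without 6 h replicate 2, 282 without 6 h replicate 1, 390 without 6 h replicate 3, 436 without vehicle replicate 1 and 1206 of the genes above the median signal. Higher genes outnumbered lower ones without 6 h replicate 2 (150 and 111) or vehicle replicate 3 (258 and 221), at an adjusted p under 0.01 (122 and 112) and at 1.5-fold or more (53 and 25), and the numbers were equal with only the compared groups in the fit (227 and 227). In all, 215 of the genes passed in all 9 fits that left out 1 array. Of the 8 shifted lists, the inflammatory one did not pass without vehicle replicate 1, 6 h replicate 2 or 24 h replicate 2 (up to 0.135) or above the median signal (0.133). The NRF2 list did not without vehicle replicate 1, 6 h replicate 1 or 24 h replicate 2 (up to 0.0805) or with probe sets averaged (0.0565), nor the nuclear receptor list without vehicle replicate 3 (0.0775) or above the median signal (0.108). The unfolded protein and amino acid stress list newly passed upward after quantile normalization (0.0466) and the circadian list downward with probe sets averaged (0.0176).

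After 24 h of GW7647, 21 of 30 measured hypoxia response genes and 9 of 22 genes of mitochondrial fatty acid oxidation were higher than in vehicle, and 12 of 31 acute phase genes were lower. With 1 array left out, the 21 hypoxia genes became 11 without 24 h replicate 1 and 12 without 24 h replicate 2, and the 9 oxidation genes became 5 without 24 h replicate 2. ASNS, which makes asparagine, was 9.06-fold (95% confidence interval 8.13 to 10.1) higher, with mean signals of 11.65 ± 0.11 against 8.47 ± 0.10 log2 units (SD, n = 3 arrays per group). CTH, which makes cysteine, was 4.21-fold (95% confidence interval 3.70 to 4.81) higher. PLIN2 was 2.81-fold (95% confidence interval 2.55 to 3.09) higher and CPT1A, the rate-controlling step of mitochondrial fatty acid oxidation, 1.70-fold (95% confidence interval 1.49 to 1.95) higher. Skeletal muscle actin ACTA1 had the largest fall, 3.21-fold (95% confidence interval 2.88 to 3.57). In all, 1616 genes passed: 1063 rose and 553 fell, 40 and 3 of them by more than 2-fold, and quantile normalization gave 1031 and 731.

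The 8 largest rises were ASNS (3.18 ± 0.07, adjusted p = 1.69e-09), CTH (2.08 ± 0.09), the activin subunit INHBE (1.87 ± 0.07), and MT1G (1.86 ± 0.08), followed by the mitochondrial folate enzyme ALDH1L2 (1.82 ± 0.15), SLC7A11 (1.82 ± 0.09), the collagen cross-linking enzyme LOX (1.77 ± 0.13) and DDIT4 (1.73 ± 0.09). A second probe set of ASNS had a log2 change of 0.16 (adjusted p = 0.379) and one of MT1G -0.06 (adjusted p = 0.749). The 6 largest falls were ACTA1 (-1.68 ± 0.07, adjusted p = 2.59e-07), IL17B (-1.14 ± 0.07), the smooth muscle protein TAGLN (-1.13 ± 0.07), the coagulation factor chain F13B (-0.96 ± 0.15), the nuclear RNA MALAT1 (-0.88 ± 0.22) and UGT2B28 (-0.88 ± 0.07). TAGLN had a log2 change of -0.13 on a probe set without shared probes, and MALAT1 did not pass without any 1 of 8 arrays, all but 24 h replicate 3 (adjusted p up to 0.125), with only the compared groups (0.0947) or without shared probes (0.0714).

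Both fatty acid oxidation lists were shifted upward at 24 h, although neither passed with an estimated correlation (adjusted p = 0.291 for each). Of 22 measured genes of mitochondrial fatty acid oxidation and the carnitine shuttle, 9 rose, 0 fell and 13 did not pass, with CPT1A (0.77 ± 0.09, adjusted p = 4.85e-04) and the electron carrier enzyme ETFDH (0.65 ± 0.07) the largest. Mitochondrial oxidation genes at 24 h had 11 up and 0 down adjusted over the list alone, with camera adjusted p = 7.90e-08 and adjusted p = 0.291 with an estimated correlation. In the peroxisomal list 5 rose, 0 fell and 17 did not pass of 22, among them catalase CAT (0.49 ± 0.06, adjusted p = 4.85e-04) and PEX11A (0.35 ± 0.07), which promotes peroxisome division. Peroxisomal genes at 24 h had 7 up and 0 down adjusted over the list alone, with camera adjusted p = 0.00710 and adjusted p = 0.291 with an estimated correlation. PEX11A did not pass without shared probes (0.19, adjusted p = 0.309). The 9 mitochondrial rises became 5 without 24 h replicate 2. The 5 peroxisomal rises became 2 without vehicle replicate 1 or 3 or 24 h replicate 2 or 3 and 3 without 6 h replicate 1. Classical PPARα targets were shifted upward, and 8 rose, 1 fell and 14 did not pass of 23. CPT1A and ETFDH are members of this list too. PPARα targets at 24 h had 9 up and 2 down adjusted over the list alone, with camera adjusted p = 8.46e-04 and adjusted p = 0.291 with an estimated correlation. PLIN2 (1.49 ± 0.06, adjusted p = 2.59e-07) rose most and VNN1 (-0.81 ± 0.07, adjusted p = 3.98e-05), an ectoenzyme known as a PPARα target in liver, fell. A second PLIN2 probe set had a value of -0.01. FABP1, the liver fatty acid-binding protein, rose by 0.31 ± 0.06 (adjusted p = 0.00673), and CREB3L3 by 0.59 ± 0.13 (adjusted p = 0.0226). CREB3L3 did not pass without vehicle replicate 1 or 3 or 24 h replicate 2 or 3 (up to 0.0890) or with only the compared groups (0.0658), nor FABP1 without shared probes (0.29, adjusted p = 0.0893). PDK4 (-0.06 ± 0.13, adjusted p = 0.858), ANGPTL4 (0.23 ± 0.10, adjusted p = 0.227) and PPARA (-0.06 ± 0.06, adjusted p = 0.655) did not pass. Omega-hydroxylation genes were shifted downward, and 0 rose, 3 fell and 8 did not pass of 11: the fatty acid hydroxylases CYP4F3 (-0.59 ± 0.09), CYP4F12 (-0.42 ± 0.06) and CYP4F2 (-0.35 ± 0.07). Omega-hydroxylation genes at 24 h had 0 up and 3 down adjusted over the list alone, with camera adjusted p = 0.0469 and adjusted p = 0.291 with an estimated correlation.

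Hypoxia response genes were shifted upward at 24 h. Hypoxia genes at 24 h had 22 up and 0 down adjusted over the list alone, with camera adjusted p = 1.78e-15 and adjusted p = 0.291 with an estimated correlation. Of 30 measured, 21 rose, 0 fell and 9 did not pass, led by the mitophagy receptor BNIP3L (1.07 ± 0.19, adjusted p = 0.00545) and the transcription factor BHLHE40 (1.04 ± 0.07). The p of this list was the smallest with camera at its preset correlation, whereas by fry the unfolded protein and amino acid stress list had the smallest (adjusted p = 5.08e-04 against 0.00371). The 21 hypoxia rises became 11 without 24 h replicate 1 and 12 without 24 h replicate 2. The angiogenic factor VEGFA rose by 0.81 ± 0.12. Glycolysis and pyruvate metabolism was shifted upward, and 8 rose, 0 fell and 25 did not pass of 33, with SLC2A3 (1.03 ± 0.06, adjusted p = 1.85e-06) the largest. Glycolysis genes at 24 h had 11 up and 0 down adjusted over the list alone, with camera adjusted p = 2.11e-04 and adjusted p = 0.291 with an estimated correlation. PFKFB3, which drives glycolytic flux, rose by 0.82 ± 0.17 (adjusted p = 0.0134). SLC2A3 and PFKFB3 are also members of the hypoxia list, so the shifts of hypoxia and glycolysis are in part the same result. Without 24 h replicate 1, PFKFB3 had an adjusted p of 0.0536. The 8 glycolysis rises became 3 without 24 h replicate 1 or 2 and 5 without vehicle replicate 1. The list of the unfolded protein and amino acid stress response was shifted upward, and 11 rose, 1 fell and 19 did not pass of 31. Unfolded protein and amino acid stress genes at 24 h had 15 up and 6 down adjusted over the list alone, with camera adjusted p = 1.53e-05 and adjusted p = 0.291 with an estimated correlation. The largest of these, ASNS, CTH, SLC7A11 and DDIT4, are known for amino acid shortage, and of 12 endoplasmic reticulum chaperone and degradation genes HERPUD1 rose (0.27 ± 0.05) and SEL1L fell (-0.23 ± 0.06). SEL1L did not pass without any 1 of 8 arrays, all but vehicle replicate 2 (adjusted p up to 0.164). Without vehicle replicate 2 the falls of the stress list numbered 4. Amino acid and urea metabolism was shifted upward too, and 7 rose, 4 fell and 28 did not pass of 39, with PHGDH (1.43 ± 0.06, adjusted p = 2.59e-07), the entry enzyme of serine synthesis, and the histidine-degrading enzyme HAL (1.37 ± 0.15) the largest. Amino acid genes at 24 h had 9 up and 4 down adjusted over the list alone, with camera adjusted p = 0.00710 and adjusted p = 0.394 with an estimated correlation. The 4 falls of amino acid genes became 2 without vehicle replicate 2 or 24 h replicate 1 or 2.

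Acute phase and complement genes were shifted downward at 24 h: 1 rose, 12 fell and 18 did not pass of 31. Acute phase genes at 24 h had 3 up and 13 down adjusted over the list alone, with camera adjusted p = 6.83e-05 and adjusted p = 0.291 with an estimated correlation. ITIH3 (-0.74 ± 0.06, adjusted p = 5.87e-05) and the fibrinogen chain FGB (-0.67 ± 0.06) fell most, and the complement protease MASP1 rose (0.56 ± 0.07). Hepatocyte identity genes were also shifted downward, and 3 rose, 4 fell and 24 did not pass of 31, with coagulation factor F5 (-0.59 ± 0.07) the largest fall and IGFBP1 (1.03 ± 0.17), which binds insulin-like growth factors, the largest rise. Hepatocyte identity genes at 24 h had 3 up and 9 down adjusted over the list alone, with camera adjusted p = 0.0427 and adjusted p = 0.325 with an estimated correlation. Nuclear receptors and coregulators were shifted upward, opposite to 6 h, and 5 rose, 0 fell and 21 did not pass of 26. Nuclear receptors at 24 h had 5 up and 0 down adjusted over the list alone, with camera adjusted p = 0.0133 and adjusted p = 0.291 with an estimated correlation. NR0B2, a repressor of bile acid synthesis, rose by 0.90 ± 0.06 (adjusted p = 5.26e-06) and PPARGC1A by 0.56 ± 0.09. Immediate early genes were shifted upward, and 9 rose, 0 fell and 21 did not pass of 30, with IER3 (0.84 ± 0.07) and the matrix-associated protein CCN2 (0.83 ± 0.06) the largest. Immediate early genes at 24 h had 10 up and 1 down adjusted over the list alone, with camera adjusted p = 2.90e-04 and adjusted p = 0.291 with an estimated correlation. The 4 falls of hepatocyte identity genes became 2 without 24 h replicate 1 or 2. The 5 rises of nuclear receptors became 2 without vehicle replicate 1 or 3 or 6 h replicate 2 or 24 h replicate 1 or 2 and 3 without 6 h replicate 1 or 3 or 24 h replicate 3. The lipoprotein receptor VLDLR, a member of the unfolded protein and amino acid stress list, rose by 1.00 ± 0.09 (adjusted p = 6.87e-05). Beyond the shifted lists, ANGPTL8 (1.22 ± 0.15), which restrains lipoprotein lipase, and PCK2 (1.03 ± 0.06), a mitochondrial enzyme of glucose production, rose.

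The limma test passed 1616 genes, against 4198 at an unadjusted p under 0.05. The 3 arrays at 24 h lay entirely above or below the vehicle arrays in 1611 of the 1616, and in 23.0% of all genes where chance gives 10%. The count was 1005 without 24 h replicate 2, 1055 without 24 h replicate 1, 1076 without vehicle replicate 1 and 921 with only the compared groups in the fit. In all, 783 genes passed in all 9 fits that left out 1 array. Of the 12 shifted lists, the omega-hydroxylation one did not pass without vehicle replicate 2, 6 h replicate 1 or 2 or 24 h replicate 1 or 2 (adjusted p up to 0.163), after quantile normalization (0.0761) or with the replicate number as a block (0.0522). The nuclear receptor list did not without vehicle replicate 2 (0.121) or above the median signal (0.199). The hepatocyte identity list did not without vehicle replicate 3 or 24 h replicate 1 or 3 (up to 0.0992), above the median signal (0.0616) or with probe sets averaged (0.280), which made the glucose production list pass upward (0.0446).

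**Figure D2:**
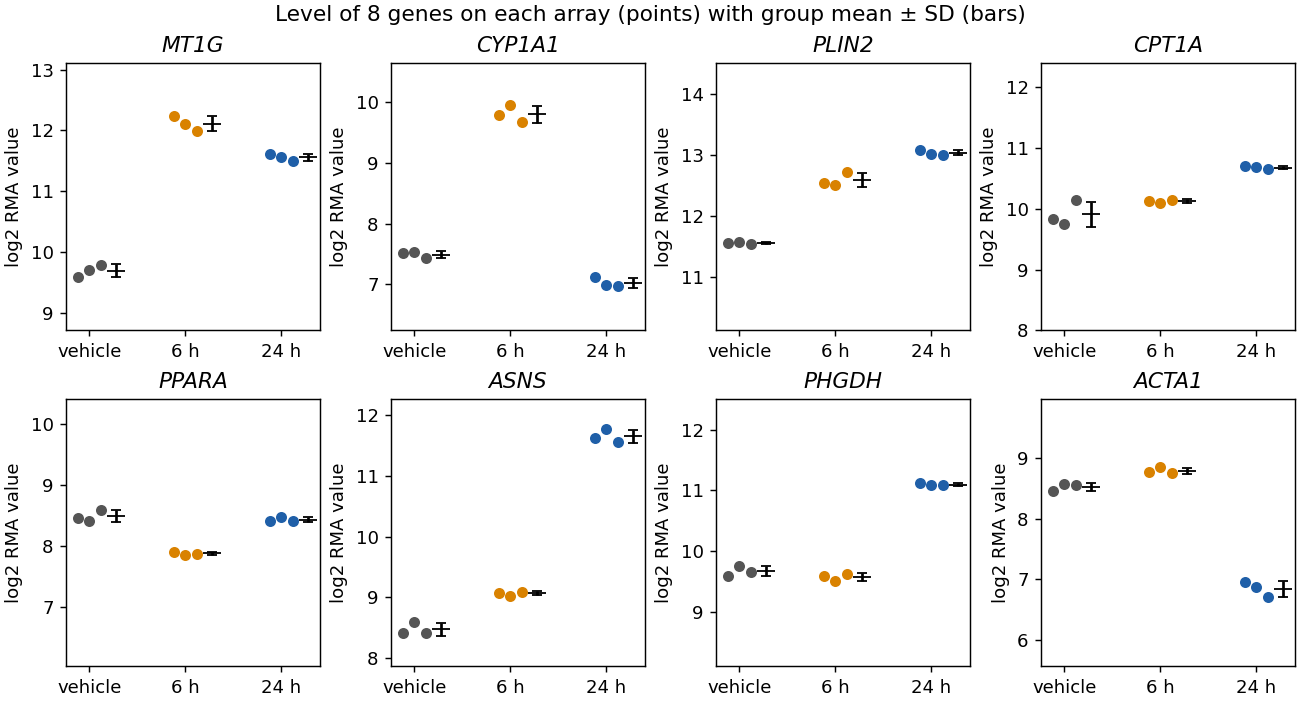
Log2 signal of 8 genes in each array (points) with the mean and SD of each group of 3 arrays (bars), every panel spanning the same range of log2 units. CYP1A1 lay at 9.80 at 6 h against 7.49 in vehicle and 7.02 at 24 h, and ASNS at 11.65 at 24 h against 8.47 in vehicle.

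**Figure D3:**
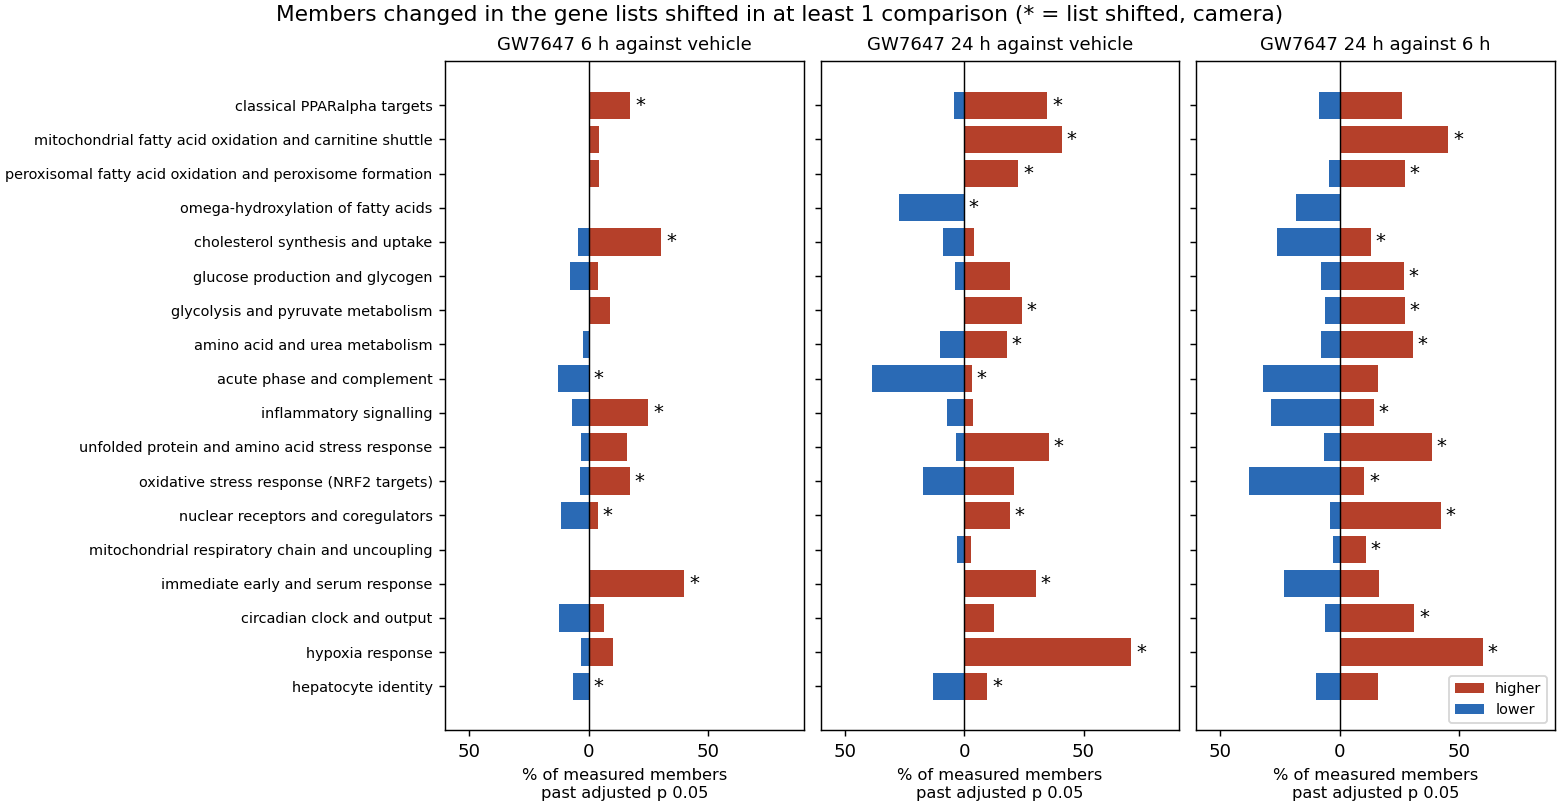
Share in percent of the measured members of 18 gene lists that were higher (right) or lower (left) at an adjusted p under 0.05 in each comparison, with a star where the list was shifted. In the hypoxia list 21 of 30 members were higher and 0 lower at 24 h than in vehicle (11 higher without 24 h replicate 1, 12 without 24 h replicate 2).

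The comparison of 24 h with 6 h of GW7647 asks how the profile changed with time among treated cells, and it equals the difference between the changes against vehicle. ASNS was 6.01-fold (95% confidence interval 5.39 to 6.70) higher at 24 h than at 6 h, with n = 3 arrays per group. CYP1A1 was 6.86-fold (95% confidence interval 6.10 to 7.71) lower, with mean signals of 7.02 ± 0.09 against 9.80 ± 0.14 log2 units (SD). The coactivator PPARGC1A, which drives genes of fasting and mitochondria, was 2.29-fold (95% confidence interval 1.99 to 2.63) higher, and the sterol enzyme HMGCS1 1.82-fold (95% confidence interval 1.64 to 2.03) lower. PLIN2 was 1.37-fold higher at 24 h. In all, 2729 genes differed: 1826 were higher and 903 lower at 24 h, 28 and 9 of them by more than 2-fold.

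The 5 largest increases from 6 h to 24 h were ASNS (2.59 ± 0.07, adjusted p = 8.09e-09), ALDH1L2 (1.89 ± 0.15), CTH (1.72 ± 0.09), LOX (1.72 ± 0.13) and the non-coding RNA LINC00115 (1.62 ± 0.08). The 5 largest decreases were CYP1A1 (-2.78 ± 0.08, adjusted p = 8.09e-09), ACTA1 (-1.94 ± 0.07), CXCL8 (-1.65 ± 0.10), TAGLN (-1.42 ± 0.07) and GPCPD1 (-1.26 ± 0.09), with TAGLN at -0.15 (adjusted p = 0.292) and ASNS at 0.12 (0.509) without shared probes. From 6 h to 24 h, 10 lists were shifted upward, fatty acid oxidation, hypoxia and amino acid metabolism among them, and 0 of the 10 passed with an estimated correlation (lowest adjusted p = 0.0980). In mitochondrial fatty acid oxidation 10 were higher, 0 were lower and 12 did not pass of 22, with ETFDH (0.57 ± 0.07) and CPT1A (0.55 ± 0.09) the largest. Mitochondrial oxidation genes between the times had 13 up and 0 down adjusted over the list alone, with camera adjusted p = 1.69e-06 and adjusted p = 0.344 with an estimated correlation. In the peroxisomal list 6 were higher, 1 was lower and 15 did not pass of 22, with CAT (0.48 ± 0.06) higher and the branched-chain acyl-CoA oxidase ACOX3 (-0.36 ± 0.06) lower. Peroxisomal genes between the times had 8 up and 1 down adjusted over the list alone, with camera adjusted p = 0.00802 and adjusted p = 0.344 with an estimated correlation. In the hypoxia list 18 were higher, 0 were lower and 12 did not pass of 30, with BNIP3L (1.201 ± 0.19, adjusted p = 0.00167) and MXI1 (0.87 ± 0.07), which opposes MYC, the largest. Hypoxia genes between the times had 22 up and 0 down adjusted over the list alone, with camera adjusted p = 2.31e-11 and adjusted p = 0.344 with an estimated correlation. Their p was again the smallest with camera at its preset correlation, whereas nuclear receptors had the smallest by fry (adjusted p = 2.68e-04 against 0.00679) and with an estimated correlation. In glycolysis 9 were higher, 2 were lower and 22 did not pass of 33, with PFKFB4 (0.78 ± 0.17) the largest. Glycolysis genes between the times had 12 up and 2 down adjusted over the list alone, with camera adjusted p = 0.0128 and adjusted p = 0.433 with an estimated correlation. With 1 array left out, the 10 mitochondrial oxidation genes that were higher became 4 without 6 h replicate 2, and the 6 peroxisomal ones became 3 without 6 h replicate 2 or 3 or 24 h replicate 2. The 9 higher glycolysis genes became 2 without 6 h replicate 1 or 2 or 24 h replicate 2 and 4 without 24 h replicate 1 or 3. The 2 lower ones became 0 without 6 h replicate 1 or 2 or 24 h replicate 1 and 1 without 6 h replicate 3 or 24 h replicate 2 or 3.

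Amino acid and urea metabolism was shifted upward from 6 h to 24 h, and 12 were higher, 3 were lower and 24 did not pass of 39, with PHGDH (1.52 ± 0.06, adjusted p = 1.96e-07) and HAL (1.31 ± 0.15) the largest. Amino acid genes between the times had 15 up and 4 down adjusted over the list alone, with camera adjusted p = 6.26e-04 and adjusted p = 0.344 with an estimated correlation. In the unfolded protein and amino acid stress list 12 were higher, 2 were lower and 17 did not pass of 31, led by ASNS and CTH. Unfolded protein and amino acid stress genes between the times had 14 up and 2 down adjusted over the list alone, with camera adjusted p = 6.15e-04 and adjusted p = 0.344 with an estimated correlation. Among nuclear receptors and coregulators 11 were higher, 1 was lower and 14 did not pass of 26, with PPARGC1A (1.19 ± 0.09, adjusted p = 2.11e-05) and NR0B2 (0.81 ± 0.06) the largest. Nuclear receptors between the times had 12 up and 1 down adjusted over the list alone, with camera adjusted p = 2.03e-05 and adjusted p = 0.0980 with an estimated correlation. In glucose production and glycogen 7 were higher, 2 were lower and 17 did not pass of 26, with PPARGC1A and PCK2 (0.97 ± 0.06) the largest. Glucose production genes between the times had 8 up and 2 down adjusted over the list alone, with camera adjusted p = 0.0330 and adjusted p = 0.404 with an estimated correlation. In the respiratory chain list 4 were higher, 1 was lower and 31 did not pass of 36, with the ATP synthase subunit ATP5MC1 (0.36 ± 0.07) higher and cytochrome c, CYCS, lower (-0.33 ± 0.06). Respiratory chain genes between the times had 4 up and 1 down adjusted over the list alone, with camera adjusted p = 0.0461 and adjusted p = 0.557 with an estimated correlation. CYCS did not pass with probe sets averaged (adjusted p = 0.109). Of the circadian clock genes 5 were higher, 1 was lower and 10 did not pass of 16, among them NFIL3 (0.49 ± 0.07) and BMAL1 (0.44 ± 0.06). Circadian genes between the times had 6 up and 2 down adjusted over the list alone, with camera adjusted p = 0.0228 and adjusted p = 0.344 with an estimated correlation. The 3 lower amino acid genes became 0 without 6 h replicate 1 or 24 h replicate 1 and 1 without 6 h replicate 2. The 11 higher nuclear receptor genes became 7 without 6 h replicate 1 or 24 h replicate 3. The 4 higher respiratory chain genes became 2 without any 1 of the 6 h arrays or 24 h replicate 2 or 3 and 7 without vehicle replicate 2.

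Lists shifted downward from 6 h to 24 h were cholesterol, inflammation and NRF2 targets, of which 0 passed with an estimated correlation. In cholesterol synthesis and uptake 3 were higher, 6 were lower and 14 did not pass of 23, with HMGCS1 (-0.87 ± 0.07, adjusted p = 3.09e-05) and IDI1 (-0.70 ± 0.06) the largest decreases. Cholesterol genes between the times had 5 up and 9 down adjusted over the list alone, with camera adjusted p = 0.0377 and adjusted p = 0.344 with an estimated correlation. On a probe set without shared probes IDI1 had a log2 change of 0.36, and with probe sets averaged it did not pass (-0.18, adjusted p = 0.0590). The 3 higher cholesterol genes became 1 without 6 h replicate 1 or 2 or 24 h replicate 2 or 3. In inflammatory signalling 4 were higher, 8 were lower and 16 did not pass of 28, with CXCL8 and CCL20 (-0.69 ± 0.06, adjusted p = 3.89e-05) lower and the interleukin receptor IL1R1 higher (0.67 ± 0.06). Inflammatory genes between the times had 4 up and 8 down adjusted over the list alone, with camera adjusted p = 0.0228 and adjusted p = 0.344 with an estimated correlation. Among NRF2 targets 3 were higher, 11 were lower and 15 did not pass of 29, with MT1X (-0.83 ± 0.08) and MT2A (-0.57 ± 0.08) the largest decreases and SLC7A11 (0.53 ± 0.09) higher. NRF2 targets between the times had 3 up and 12 down adjusted over the list alone, with camera adjusted p = 0.0128 and adjusted p = 0.414 with an estimated correlation.

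The limma test passed 2729 genes, against 5117 at an unadjusted p under 0.05. The arrays of the compared times lay entirely apart in 2719 of the 2729, and in 33.0% of all genes where chance gives 10%. The count was 1519 without 6 h replicate 2, 1739 without 6 h replicate 1 and 1774 without probe sets that share probes, and 1362 genes passed in all 9 fits that left out 1 array. After quantile normalization 1457 genes were higher and 1207 lower, and after median centring 2175 and 653. Of the 13 shifted lists, some did not pass without 1 array, cholesterol without 6 h replicate 3 or 24 h replicate 1 (adjusted p up to 0.0848) and glucose production without 6 h replicate 2 or 24 h replicate 1 (up to 0.0532). The respiratory chain did not without 6 h replicate 2 or 3 or 24 h replicate 2 (up to 0.154). With the replicate number as a block, cholesterol and the respiratory chain did not pass (0.0562 for each). Glucose production (0.0601) and the respiratory chain (0.357) did not pass after quantile normalization. Cholesterol (0.160), inflammatory (0.0563) and NRF2 (0.0627) lists did not with probe sets averaged, which made the PPARα target list pass upward (0.0240). Above the median signal 6 of the 13 passed, and the peroxisomal (0.0932), glucose production (0.546), glycolysis (0.0559), inflammatory (0.163), unfolded protein and amino acid stress (0.0692), respiratory chain (0.371) and circadian (0.357) lists did not.

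Both treated groups were set against the same 3 vehicle arrays, so their changes are related by construction. Among genes that passed at both times, 106 rose at both, PLIN2, SLC7A11 and DDIT4 among them, and 47 fell at both, where independent calls would give 17.4 and 10.5. A further 16 rose at 6 h and fell at 24 h, as CYP1A1 did (2.31 ± 0.08 and -0.47 ± 0.08), where independent calls would give 9.06. Another 38 fell and then rose, as PPARGC1A did (-0.64 ± 0.09 and 0.56 ± 0.09), where they would give 20.3. Across genes the log2 changes at 6 h and at 24 h correlated at r = 0.289 and rho = 0.272. Simulated unchanged groups that shared the vehicle arrays gave r = 0.500 (0.485 to 0.513 over 100 runs) and rho = 0.477, and the observed covariance was 0.00701 against a simulated 0.00320. The simulation gave a gene the same spread in all groups, whereas the median SD of a gene was 0.089 in vehicle, 0.060 at 6 h and 0.075 at 24 h. The simulated correlation and covariance may therefore be too low. The simulated groups hold no effects and gave 0 genes passing at both times in 1 direction. They do not measure how much the shared arrays add among the 153 that did. Part of the excess over independent calls may come from the shared controls, since 3 vehicle arrays cannot be split into separate sets of at least 2. Without 6 h replicates 1, 2 and 3 in turn the count of 153 was 72, 74 and 78, and without vehicle replicate 1, 24 h replicate 1 and 24 h replicate 3 it was 95, 96 and 101.

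**Figure D4:**
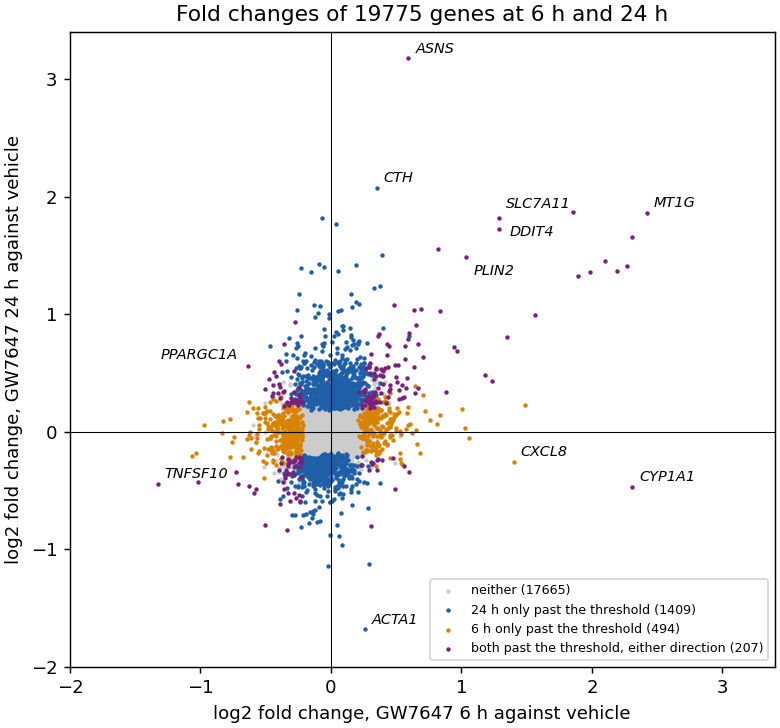
Log2 change against vehicle at 6 h (horizontal) and at 24 h (vertical) for 19775 genes, with 494 genes past the threshold at 6 h only, 1409 at 24 h only and 207 at both, in either direction. ASNS sits at 3.18 on the vertical axis and CYP1A1 at 2.31 on the horizontal axis.

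Of the 29 gene lists, 8 were shifted at 6 h (5 upward, 3 downward), 12 at 24 h (9 upward, 3 downward) and 13 between the times (10 upward, 3 downward). Some lists share members, so these counts do not number independent results. With an estimated correlation 0 passed in each comparison, and the lowest adjusted p was 0.137, 0.291 and 0.0980. Of the lists shifted at 6 h and at 24 h, 4 went the same way, and nuclear receptors went down and then up. The other 11 lists were not shifted in any comparison. Of 6 ketone body genes, 0 rose and 1 fell at 6 h, 0 and 0 at 24 h, and 0 were higher and 0 lower at 24 h than at 6 h. Ketone body counts adjusted over the list alone were 0 and 1, 0 and 0, and 3 and 0, with camera adjusted p = 0.130, 0.866 and 0.127. Of 27 lipid droplet and triglyceride genes, 4 rose and 0 fell at 6 h, 5 and 2 at 24 h, and 4 were higher and 3 lower at 24 h than at 6 h. Lipid droplet and triglyceride counts adjusted over the list alone were 4 and 0, 5 and 2, and 4 and 3, with camera adjusted p = 0.589, 0.528 and 0.907. PLIN2 and the acyltransferase GPAT3 (0.49 ± 0.09) were its largest changes at 6 h, and GPAT3 did not pass without 6 h replicate 1 or 3 (up to 0.0567). Of 25 fatty acid uptake and activation genes, 1 rose and 0 fell at 6 h, 2 and 0 at 24 h, and 4 were higher and 3 lower at 24 h than at 6 h. Fatty acid uptake and activation counts adjusted over the list alone were 1 and 0, 2 and 0, and 5 and 3, with camera adjusted p = 0.589, 0.567 and 0.907. Of 19 fatty acid synthesis genes, 0 rose and 0 fell at 6 h, 2 and 2 at 24 h, and 5 were higher and 2 lower at 24 h than at 6 h. Fatty acid synthesis counts adjusted over the list alone were 0 and 0, 2 and 2, and 5 and 2, with camera adjusted p = 0.943, 0.614 and 0.714. PNPLA3, a lipid droplet hydrolase of that list, rose at 24 h (0.50 ± 0.08). Of 25 apolipoprotein and lipoprotein genes, 1 rose and 0 fell at 6 h, 2 and 1 at 24 h, and 2 were higher and 2 lower at 24 h than at 6 h. Apolipoprotein and lipoprotein counts adjusted over the list alone were 1 and 0, 2 and 2, and 2 and 2, with camera adjusted p = 0.648, 0.807 and 0.907. Endothelial lipase LIPG rose at 6 h (0.59 ± 0.09) and the apolipoprotein APOM fell at 24 h (-0.59 ± 0.06). The 4 rises of lipid droplet genes at 6 h became 1 without 6 h replicate 1 or 3. The 5 rises of lipid droplet genes at 24 h became 3 without vehicle replicate 1 or 3 or 6 h replicate 1 or any 1 of the 24 h arrays. The 4 fatty acid uptake genes higher at 24 h than at 6 h became 2 without 6 h replicate 2 or 3 or 24 h replicate 1 or 2. The 5 fatty acid synthesis genes higher at 24 h than at 6 h became 2 without 6 h replicate 1 or 2 or 24 h replicate 1 or 3 and 3 without 6 h replicate 3 or 24 h replicate 2.

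Of 26 bile acid genes, 0 rose and 2 fell at 6 h, 5 and 2 at 24 h, and 8 were higher and 2 lower at 24 h than at 6 h. Bile acid counts adjusted over the list alone were 0 and 2, 6 and 6, and 8 and 3, with camera adjusted p = 0.05004, 0.567 and 0.454. The bile acid value at 6 h lay just above the threshold, and was 0.0466 after quantile normalization. SLC51A, a bile acid transporter subunit, rose at 24 h (0.70 ± 0.14). Of 35 interferon response genes, 0 rose and 0 fell at 6 h, 5 and 2 at 24 h, and 5 were higher and 1 lower at 24 h than at 6 h. Interferon response counts adjusted over the list alone were 0 and 0, 6 and 2, and 5 and 1, with camera adjusted p = 0.648, 0.344 and 0.715. TRIM22, an interferon-induced ligase, fell at 24 h (-0.81 ± 0.07). Of 26 drug metabolism genes, 1 rose and 3 fell at 6 h, 1 and 4 at 24 h, and 4 were higher and 3 lower at 24 h than at 6 h. Drug metabolism counts adjusted over the list alone were 1 and 3, 1 and 5, and 4 and 4, with camera adjusted p = 0.648, 0.208 and 0.360. The monooxygenase FMO5 fell at 6 h (-0.55 ± 0.08) and the efflux pump ABCB1 at 24 h (-0.59 ± 0.05). With probe sets averaged the drug metabolism list passed at 24 h (adjusted p = 0.0458). Of 35 cell cycle genes, 1 rose and 0 fell at 6 h, 3 and 6 at 24 h, and 7 were higher and 7 lower at 24 h than at 6 h. Cell cycle counts adjusted over the list alone were 1 and 0, 6 and 10, and 12 and 8, with camera adjusted p = 0.322, 0.309 and 0.907. The mitotic kinase CDK1 fell at 24 h (-0.41 ± 0.06). Of 21 growth arrest and p53 genes, 1 rose and 2 fell at 6 h, 2 and 3 at 24 h, and 4 were higher and 4 lower at 24 h than at 6 h. Growth arrest and p53 counts adjusted over the list alone were 3 and 7, 4 and 4, and 4 and 5, with camera adjusted p = 0.186, 0.567 and 0.907. PMAIP1, which promotes cell death, rose at 6 h (0.65 ± 0.08), and the antiproliferative BTG1 rose at 24 h (0.53 ± 0.09). BTG1 did not pass without shared probes (0.039, adjusted p = 0.818). Of 28 other liver cell type genes, 2 rose and 1 fell at 6 h, 2 and 0 at 24 h, and 2 were higher and 1 lower at 24 h than at 6 h. Other liver cell type counts adjusted over the list alone were 2 and 1, 2 and 0, and 2 and 1, with camera adjusted p = 0.521, 0.689 and 0.907. The 5 interferon genes that rose at 24 h became 2 without vehicle replicate 3 and 3 without vehicle replicate 1 or 6 h replicate 2 or 3 or 24 h replicate 2. The 5 interferon genes higher at 24 h than at 6 h became 2 without 6 h replicate 2 or 3 and 3 without 24 h replicate 3. The 4 falls of drug metabolism genes at 24 h became 2 without 24 h replicate 2. The 7 cell cycle genes higher at 24 h than at 6 h became 3 without 6 h replicate 1 or 2 or 24 h replicate 2 and 4 without 6 h replicate 3. The 7 cell cycle genes lower at 24 h than at 6 h became 4 without 6 h replicate 1 or 2 or 24 h replicate 1 or 3. The 4 growth arrest genes lower at 24 h than at 6 h became 1 without 6 h replicate 1 and 2 without 6 h replicate 2 or 24 h replicate 1. Of the lists not shifted, counts of 3 or fewer ran from 0 to 5 with an array left out. The median, the mean and the test of a list differed in sign for 9 lists at 6 h, 5 at 24 h and 4 between the times, 0 of them among the shifted lists. At 6 h these were omega-hydroxylation, lipid droplet, fatty acid uptake, fatty acid synthesis, apolipoproteins, glycolysis, unfolded protein and amino acid stress, drug metabolism and hypoxia. At 24 h they were lipid droplet, fatty acid synthesis, apolipoproteins, NRF2 and circadian lists. Between the times they were fatty acid uptake, bile acid, interferon and growth arrest.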

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

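The shared-probe, completion-by-6 h, culture-time and aryl hydrocarbon receptor tests below were chosen only after the result was seen. The change against vehicle differed between 24 h and 6 h for 2729 of 19775 genes in the limma test of the difference itself, and for 96 of 109 named genes (highest adjusted p = 0.0455). Apart from the genes always named, the 109 were picked for large changes against vehicle on these same arrays. Their high share follows in part from that choice. The difference of the log2 changes, 24 h minus 6 h, was positive for 51 of the 96 and negative for 45.

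The largest positive differences were ASNS 2.59, ALDH1L2 1.89, CTH 1.72, LOX 1.72, PHGDH 1.52, HAL 1.31, IGFBP1 1.29, BNIP3L 1.201, PPARGC1A 1.19, SLC1A2 1.04, VLDLR 1.01, PCK2 0.97 and ANGPTL8 0.89. Next came TNFSF10 0.88, PTCHD4 0.86, C9orf152 0.86, TOX3 0.82, NR0B2 0.81, BTG1 0.67, TP53INP1 0.67, CEBPD 0.63, FOXA2 0.59, PPP1R16A 0.59, RXRA 0.58, FMO5 0.57 and ETFDH 0.57. Below these were PPARA 0.55, CPT1A 0.55, SLC51A 0.55, SLC7A11 0.53, CCNB2 0.52, IFIT1 0.49, CAT 0.48, CCN2 0.46, PLIN2 0.45, BMAL1 0.44, DDIT4 0.44, FOXA3 0.43 and DBP 0.41. The smallest were PNPLA3 0.41, ACTA2 0.39, FABP1 0.37, KLB 0.35, BHLHE40 0.35, UCP2 0.33, C4BPB 0.32, SREBF2 0.28, CD14 0.28, HP 0.27, IER3 0.25 and SLC2A3 0.19.

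The largest negative differences were CYP1A1 -2.78, ACTA1 -1.94, CXCL8 -1.65, TAGLN -1.42, IL17B -1.12, VNN1 -1.11, F13B -1.05, MALAT1 -0.94, UGT2B28 -0.87, HMGCS1 -0.87, MT1E -0.86 and MT1X -0.83. Next came AQP3 -0.82, EGR1 -0.81, IDI1 -0.70, CCL20 -0.69, MT1F -0.65, MT1H -0.64, STARD4 -0.63, MT1HL1 -0.63, APOM -0.60, ITIH3 -0.59, TRIM22 -0.59 and MT2A -0.57. Below these were MT1G -0.55, FGB -0.54, LIPG -0.54, IL32 -0.52, CYP4F3 -0.52, CCNE1 -0.52, SLC2A2 -0.51, FAS -0.49, CDK1 -0.48, ACSL1 -0.47, KRT23 -0.47 and F5 -0.47. The smallest were FADS3 -0.40, ACOX3 -0.36, ABCB1 -0.35, GPAT3 -0.35, CYCS -0.33, PMAIP1 -0.32, ARG2 -0.28, PFKP -0.27 and ABCC2 -0.24.

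Of the 96 genes, 84 passed in all 9 fits that left out 1 array and 12 did not. Without any 1 of the 6 treated arrays GPAT3 did not pass (adjusted p up to 0.0886). The fits without 6 h replicate 1 or 2 or 24 h replicate 1 or 2 ended the calls of ABCC2 (0.0940), MALAT1 (0.0742) and SLC51A (0.0978), and of SREBF2 (0.101), which also failed without 24 h replicate 3. SLC2A3 (0.165) failed without vehicle replicate 1 or 3, 6 h replicate 1 or 2 or any 1 of the 24 h arrays. PFKP (0.0757) and IER3 (0.122) failed without any 1 of the 6 h arrays or 24 h replicate 1 or 3, and HP (0.0920) without any 1 of the 6 h arrays or 24 h replicate 2 or 3. ARG2 (0.113) failed without 6 h replicate 1 or 2 or 24 h replicate 1 or 3, PMAIP1 (0.0956) without 6 h replicate 1 or 3 or 24 h replicate 1 or 2, and IFIT1 (0.105) without 6 h replicate 2 or 3 or 24 h replicate 3. With probe sets averaged ACTA2 (0.108), CYCS (0.109), IDI1 (0.0590) and TP53INP1 (0.421) did not pass, and without shared probes ASNS (0.509), TAGLN (0.292), IDI1 (0.0845) and BTG1 (0.899) did not. Both alternatives were run for this difference only in the genes named for 24 h against 6 h. Against vehicle and without shared probes, MT1G changed by 0.14 at 6 h and -0.060 at 24 h, and CEBPD by -0.066 at 24 h.

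Metallothioneins rose at 6 h, and 10 of 10 of their probe sets with a shared-probe ending were higher. Glucocorticoid exposure needed a general rise of its targets, but 5 measured targets had a median log2 change of 0.083, 0 of them rose, and KLF9 fell (-0.57). TSC22D3 (upper 95% bound 0.33), ZBTB16 (0.39) and TAT lay below the median signal. The test rests on the brighter FKBP5 (0.10, upper bound 0.21) and KLF9, so it does not exclude glucocorticoid exposure. Metal reaching the cells remains open: SLC30A1, a zinc exporter under the same metal-responsive factor, rose by 0.43 ± 0.06 at 6 h (adjusted p = 0.00450) and had -0.10 at 24 h (adjusted p = 0.408), which is consistent with a metal signal but does not show its source, and a ligand effect on zinc was not tested. Shared probes also stay open as a reason why so many members were higher. The 4 probe sets without such endings had a median change of 0.125, which met the prediction written for this cause. That median cannot decide it, because 0 of the 4 lay above the median signal, a condition applied after the value was seen. The 4 read MT3 (-0.002), MT4 (0.11), MT1G (0.14) and MT1M, which rose by 1.57. MT3 and MT4 have no probe set among the 10 with the ending, so their values do not bear on those rises.

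Of 31 unfolded protein and amino acid stress genes 11 were higher and 1 lower at 24 h than in vehicle, and of 30 hypoxia genes 21 were higher and 0 lower; neither list passed with an estimated correlation (adjusted p = 0.291 for each). The 21 became 11 and 12 without 24 h replicates 1 and 2, and the 1 lower stress gene became 4 without vehicle replicate 2 and 0 without any other array. For the higher genes a response already complete by 6 h is argued against. With 1 of the 24 h arrays left out of their choice, the 22, 22 and 28 genes then higher differed between that array and the 6 h arrays by medians of 0.66, 0.64 and 0.470 (lowest interval 0.23 to 0.74), and 22, 22 and 27 of them were higher on it. Over all 31 measured stress genes the median change from 6 h to 24 h was 0.089, so this does not extend to the whole list. Unfolded protein stress is argued against for the endoplasmic reticulum part, as 12 chaperone and degradation genes had a median change of -0.17 at 24 h (interval -0.23 to -0.01). The intervals given here run over genes, which are not independent replicates. Time in culture, with medium used up and cells dense, and the ligand cannot be told apart, because 0 vehicle arrays have a stated duration; both may contribute.

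CYP1A1 rose at 6 h and then lay lower than in vehicle at 24 h. The rise did not rest on 1 array: its log2 change lay between 2.24 and 2.38 over the 9 fits that left out 1 array (highest adjusted p = 2.01e-06). Activation of the aryl hydrocarbon receptor, its usual inducer, and an effect of GW7647 on CYP1A1 cannot be told apart: of 2 other targets above the median signal 0 rose, but TIPARP had a log2 change of 0.17 with an upper bound of 0.30, too near the limit set to exclude a rise.

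Among the 10 splits of 6 arrays into 3 and 3, the real one gave 701 genes at 6 h, 1616 at 24 h and 2729 between the times, and the highest other gave 0 in each in limma. For shifted lists the real splits gave 8, 12 and 13, and the highest others 8, 3 and 8. As large a count of genes was met in 1 split of 10 each time, the real one, and of lists in 2, 1 and 1; 10 splits are too few for a share under 0.05. The 153 genes changed at both times were matched in 3 of 100 regroupings of the 9 arrays, the real one included. This share lies under the 0.05 set beforehand, which argues against a random grouping but does not exclude it. The count does not measure a shared response, because a whole group kept as the common control can also reach it. The highest other, 762, took the 24 h arrays as the common control and another, 171, the 6 h arrays. Both point to the 3 groups as a structure of the samples. The vehicle arrays as control with the treated arrays mixed gave 24, and 96 of the 99 others gave 0.

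Among 13522 probe sets without a single gene symbol, which no comparison above used, 111 passed at 6 h, 364 at 24 h and 568 between the times (0.821%, 2.69% and 4.20%, against 1.68%, 4.95% and 8.79% of those with a single symbol).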

How the results depend on the processing

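All the alternatives here were planned, so none was chosen only after the result was seen. Quantile normalization kept direction and side of the threshold for 183 of 183 named values; 2537 of 2697 did over quantile normalization, the block, the compared groups alone, the trend with robust prior, the mean of probe sets, no shared probes (135 values) and the 9 fits with an array left out. Of the others 149 no longer passed, 2 newly passed and 9 changed sign. The remaining alternatives were not run for named values. Signals near background limit dim genes such as PDK4. Where no reason is given below, the cause was not tested.

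The 701 genes at 6 h became 427 with the replicate number as a block, 454 with only the 2 compared groups in the fit, 1104 with an intensity trend and robust prior, 1206 above the median signal (fewer genes tested) and 454 without probe sets that share probes. The stricter limits, by their construction, left 234 at an adjusted p under 0.01 and 78 at 1.5-fold (53 higher and 25 lower). The 1616 genes at 24 h became 921 with only the compared groups, 695 under 0.01 and 173 at 1.5-fold. The 2729 genes between the times became 1774 without shared probes, 4181 probe sets tested on their own, 1328 under 0.01 and 267 at 1.5-fold, and of the 2664 that passed after quantile normalization 54.7% were higher at 24 h, against 66.9%. The 153 genes changed at both times became 97 with the block and 300 above the median signal. Of shifted lists 0, 0 and 0 were left with an estimated correlation, and 6 of the 13 between the times above the median signal; fry gave 12, 14 and 17.

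Replicate numbers gave no sign of pairing: 9 same-numbered pairs had residual correlations of -0.20 to 0.09. This does not exclude pairing, which the labels leave open. Vehicle replicate 3 had -0.24 with 24 h replicate 1 and 0.25 with 24 h replicate 2. With the block, 1216 genes passed at 24 h and 2197 between the times, 8, 11 and 11 lists were shifted, and 175 of 183 named values kept their side. With each array left out the counts ran from 261 (without 6 h replicate 2) to 637 at 6 h, 1005 (without 24 h replicate 2) to 1664 at 24 h, 1519 (without 6 h replicate 2) to 3082 between the times, and 72 (without 6 h replicate 1) to 160 at both times. Shifted lists ran from 6 to 10, 10 to 13 and 11 to 13. The correlation of the changes ran from 0.245 to 0.380, and was 0.338, 0.340 and 0.380 without vehicle replicates 1, 2 and 3.

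Without shared probes, IDI1 became -0.038 at 6 h and 0.36 between the times, MT1G -0.060 and CEBPD -0.066 at 24 h, and BTG1 -0.021 between the times, where another probe set stood for the gene. Of genes that did not pass, ANGPTL4 at 6 h ran from -0.13 to 0.082 with an array left out (positive without vehicle replicate 2 or 6 h replicate 2), PDK4 at 6 h from -0.10 (without vehicle replicate 3) to 0.23, and PDK4 at 24 h from -0.20 to 0.13 (without vehicle replicate 2). CPT1A at 6 h passed with probe sets averaged (0.27, adjusted p = 0.0309).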

Other observations

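The gene groups in this part, and the test of cytosolic against mitochondrial enzymes, were chosen only after the result was seen, with 8 added lists tested by camera. Of 12 measured enzymes of serine synthesis and folate one-carbon metabolism, which feed nucleotide and glutathione synthesis, 7 rose, 0 fell and 5 did not pass at 24 h, with a median log2 change of 0.50 (adjusted p = 3.10e-07; adjusted p = 0.0143 with an estimated correlation). PHGDH (1.43), PSAT1 (0.82), SHMT2 (0.81), MTHFD2 (1.10) and ALDH1L2 (1.82) were among them. Between 6 h and 24 h 7 of the 12 were higher and 0 lower (adjusted p = 1.60e-05; adjusted p = 0.0333 with an estimated correlation). PHGDH and ALDH1L2 had prompted the list, and without them 5 of 10 rose at 24 h (adjusted p = 7.90e-04; adjusted p = 0.0591 with an estimated correlation, which did not pass) and 5 were higher between the times (adjusted p = 0.00817; adjusted p = 0.0789). PSAT1, PSPH, SHMT1 and SHMT2 were also in the planned amino acid list, whose values were known when this list was made. Leaving out PHGDH and ALDH1L2 therefore does not free these p-values from a choice made on the same data. Of 10 metallothionein genes 8 were higher at 6 h and at 24 h than in vehicle, and 8 were lower at 24 h than at 6 h. Their rises had prompted that list, so no test of it is given. Because 7 of the 8 genes are read by probe sets with shared probes, they may not be separate rises. The 4 probe sets without shared probes, for MT1G, MT1M, MT3 and MT4, had a median change of 0.125 at 6 h. As 0 of the 4 lay above the median signal, that median does not decide it.

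Of 18 measured actin and serum response factor targets, genes of the cytoskeleton and of contraction, 7 rose, 0 fell and 11 did not pass at 6 h (adjusted p = 1.72e-07; adjusted p = 0.0661 with an estimated correlation), THBS1 by 0.56 and PALLD by 0.49 among them. The 7 rises became 3 without vehicle replicate 1 or 6 h replicate 1 or 2 and 4 without vehicle replicate 2 or 6 h replicate 3. At 24 h 2 rose, 5 fell and 11 did not pass (adjusted p = 0.00151; adjusted p = 0.143 with an estimated correlation). ACTA1 (-1.68), TAGLN (-1.13), MYL9 (-0.51), PALLD (-0.49) and THBS1 (-0.29) were lower than in vehicle, TAGLN at -0.13 without shared probes. FHL2 rose at both times (0.40 and 0.47), and ACTA2 rose at 24 h (0.27), though not with probe sets averaged (adjusted p = 0.174). Between the times 1 was higher and 10 were lower (adjusted p = 5.22e-08; adjusted p = 0.0567 with an estimated correlation). With an estimated correlation the full list passed in 0 comparisons. Without ACTA1, ACTA2 and TAGLN, named before the list was made, 7 of 15 rose at 6 h (adjusted p = 0.0442 with an estimated correlation), at 24 h 1 rose and 3 fell (0.208), and between the times 0 were higher and 8 lower (0.0570). The list was still chosen after the results were seen, so these p-values are not free of that choice.

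Aminoacyl-tRNA synthetases charge tRNAs with amino acids. Of 17 listed as cytosolic, 11 were higher at 24 h than in vehicle and 1, FARSB (-0.20), was lower. Of 15 listed as mitochondrial, each with a separate gene, 0 passed. The cytosolic list had a camera adjusted p = 2.90e-08, and adjusted p = 0.0642 with an estimated correlation. An enzyme serving both places from 1 gene would be counted as cytosolic, so the lists may not be fully separate. CARS1 (1.06), YARS1 (1.04), GARS1 (0.87) and AARS1 (0.72) rose most. FARSB did not pass without any 1 of the 9 arrays, and of the mitochondrial enzymes 1 rose without vehicle replicate 2 or 24 h replicate 3 and 1 fell without 24 h replicate 2. The median log2 change was 0.42 for the cytosolic and 0.07 for the mitochondrial enzymes, a difference of 0.35 (two-sided permutation p = 0.0083, 100000 resamples over genes, which are not independent replicates). Whether the ligand or time in culture started these rises was not tested.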
